A study of Homo sapiens with 4 samples.

How the data were processed

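RNA of 4 samples was measured on 2-colour Agilent oligonucleotide arrays, 1 array per sample. RC-K8, an established cell line from diffuse large B-cell lymphoma, and RC-K8-R, a derivative selected for resistance by exposure to rising amounts of interleukin-21 (IL-21) over 10 weeks, were each left untreated or given IL-21 at 100 ng/mL for 6 h. Per the labels, total RNA was extracted with Trizol, sample cDNA carried Cy5, and a common human reference RNA carried Cy3 on every array. The design has 1 array per group and no replicates, so no test between groups was run and no p-value is given.

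The deposited values are 1 log ratio per probe and array, and are read here as log2 of sample over reference. The deposited table does not state the log base, the centring or the direction, and the scanner, background correction, normalization and spot filter are not given in the sources used here. The values ran from -10.4 to 7.94 with both signs, which left out a linear ratio and log10 but not a natural log; under a natural log every fold would be larger and every direction the same. The direction followed from the dyes in the labels and was checked on marker genes of B cells and of other cell types. Array medians were -0.107 for untreated RC-K8, -0.123 for treated RC-K8, -0.106 for untreated RC-K8-R and -0.111 for treated RC-K8-R. Blank cells, which are values missing from the deposited table, numbered 5604, 5849, 5035 and 4540 in that order, and 2799 probes were blank on all 4 arrays.

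The table held 31095 probes. The platform annotation gave 1 gene symbol for 25570 probes and several for 28, and did not list 5497, which stayed unnamed. Of these probes, 25541 matched a gene by its Entrez number in a RefSeq gene table of assembly GRCh38.p14, used for names only, and no symbol needed an update. Names from that annotation can be old. No genome build is named in the sources used here, so no coordinates are given.

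Each array was centred on its median over the 23260 probes with a value on all 4 arrays. Differences between arrays were taken probe by probe and summarised per gene by the median over its probes, so that no probe's level was set against another's. This gave 13446 genes with a value on all 4 arrays, 9067 of them from 1 probe and 4379 from 2 or more. Levels are given as centred log2 ratios to the reference. Genes were counted as different at an absolute log2 difference of 1 or more, which is 2-fold. The only error available for a gene was the SD between its probes, which covers probe differences and not differences between cultures. The number of arrays limits the precision.

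There were 5 comparisons: IL-21 against untreated in each line, the difference of these responses, and RC-K8-R against RC-K8 without and with IL-21. There were 16 gene lists: IL-21 receptor and JAK-STAT components, STAT-induced feedback and early target genes, interferon-stimulated genes, MYC targets, anti-apoptotic genes, pro-apoptotic BCL2 family genes, death receptor and caspase genes, cell cycle genes, CDK inhibitors, p53 targets, NF-kappaB targets, germinal centre B cell genes, plasma cell differentiation genes, antigen presentation genes, stress and unfolded protein response genes, and ribosomal protein genes. There were also 6 marker lists, for B cells, T and NK cells, myeloid cells, epithelial cells, fibroblasts and hepatocytes. For each list the median difference of the measured members was placed among 10000 random lists of the same size matched on mean log2 ratio in 20 bins, as a description of these arrays. Over 22 lists and 5 comparisons, 110 such percentiles were computed, of which 21 lay outside the middle 95%, where 5.50 would be expected by chance for independent lists.

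The genes named for each comparison were the 10 highest and 10 lowest in the IL-21 comparison of each line and in the comparison of untreated lines, and the 5 highest and 5 lowest in the remaining comparisons, among genes whose probes all had the same direction. Transcripts with only a locus number or open reading frame name were ranked but need not be named. To these were added genes of the study's subject (MYC, BCL2, BCL2L1, BCL2L11, STAT3, SOCS1, SOCS3, IL21R, IL2RG, JAK1, JAK3, PRDM1 and BCL6; 1 further gene is not reported here) and list members at 2-fold or more. The groups, comparisons, lists, the rule for named genes and 13 alternative settings were fixed before the data were examined. A further setting, 7 gene lists and the genes named from those lists were chosen after values had been seen.

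The alternatives were the values without centring, quantile normalization, equal median absolute deviation per array, and a loess correction of each difference on the mean log2 ratio (span 0.3, 3 iterations). Further alternatives were the mean of the probes, the probe with the highest mean ratio, every probe as its own feature, genes with a value on the arrays compared, thresholds of 1.5-fold and 3-fold, and only genes with 2 or more probes in the same direction. The remaining ones were random lists without matching and the natural log reading. The added setting kept only genes with a mean log2 ratio of -2 or more.

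The procedure was tested on simulated data. For IL-21 in RC-K8, over 13446 genes, it recovered at 2-fold 100% of 50 genes made to differ by a log2 of 2.00 and 96.0% of 50 genes made to differ by 1.50, each upward, and the same shares downward. Of 13246 genes left unchanged, 97 reached 2-fold there, or 0.732%, 94 for IL-21 in RC-K8-R, 223 (1.68%) for the difference of responses, 93 for untreated lines and 86 for treated lines. The observed counts were 416, 127, 641, 1818 and 2393 in that order. The simulated noise was drawn from the differences between the RC-K8-R arrays, so the count for IL-21 in RC-K8-R follows from the data it is set against, and any response there counts as noise. All simulated arrays had the same noise, drawn for each probe separately and alike at every level, and no difference in ratio range. In the data, 77.2% of the 2-fold genes for IL-21 in RC-K8-R had a mean log2 ratio below -2, against 8.63% of all genes. The simulated shares therefore do not describe genes far below the reference. The median SD between probes of a gene was 0.119 for IL-21 in RC-K8-R, but 0.306 and 0.308 for untreated and treated lines. The simulated counts for the line comparisons may thus be too low, and do not measure noise there. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.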

Results

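Gene expression was compared in RC-K8, a diffuse large B-cell lymphoma line that undergoes apoptosis with IL-21, and RC-K8-R, its derivative selected for resistance. IL-21 is a cytokine that signals through the receptor chains IL21R and IL2RG, the kinases JAK1 and JAK3, and STAT transcription factors. Each line was measured untreated and after 6 h of IL-21, with 1 array per group and no replicates. All differences below are therefore differences between single arrays, with no estimate of the spread between cultures.

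The arrays carried values for 25491 probes in untreated RC-K8, 25246 in treated RC-K8, 26060 in untreated RC-K8-R and 26555 in treated RC-K8-R. The SD of the log2 ratios was 1.26, 1.30, 1.5 and 1.54 in that order, so the RC-K8-R arrays had the wider range. B cell markers had median log2 ratios to the reference of 1.56, 1.37, 1.77 and 2.13. Hepatocyte markers lay between -5.21 and -6.40, fibroblast markers between -4.12 and -5.44, epithelial markers between -2.73 and -4.97 and T and NK cell markers between -2.09 and -3.06, the direction that sample over reference gives for a B cell line. Myeloid markers were an exception, near the reference at 0.22 and 0.34 on the RC-K8 arrays and -0.51 and -0.44 on those of RC-K8-R. Across probes, the correlation between untreated and treated arrays was 0.942 in RC-K8 and 0.983 in RC-K8-R, and between arrays of different lines 0.851 to 0.881. Probes are not independent replicates.

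The first comparison was IL-21 against untreated in RC-K8. IL-21 treated RC-K8 had higher MYC, a transcription factor that drives growth, higher SOCS3, a feedback inhibitor of cytokine signalling, and higher ribosome biogenesis and metabolic genes that MYC regulates. It had lower BCL2L1, which encodes the survival protein BCL-XL, and lower B cell receptor component CD79B. SOCS3 was 8.77-fold higher on 1 probe (log2 3.13), MYC 8.11-fold higher as the median of 3 probes, and BCL2L1 3.18-fold lower on 2 probes (log2 -1.67, SD between probes 0.16). The 3 MYC probes differed: 2 gave 3.02 and 3.74 and the other -0.08, so the value rests on the first 2. In all, 193 genes were 2-fold higher and 223 were 2-fold lower, of 13446.

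The 10 highest genes of RC-K8 with IL-21 were ZBED2 (log2 3.42), the kinase SGK1 (3.27), SOCS3, CEMIP2 (3.13), the sphingosine-1-phosphate receptor S1PR1 (3.08), the transcriptional repressor HIC1 (3.04), the AP-1 family factor BATF3 (2.86), ZIC1 (2.74), JMY (2.5) and NAMPT (2.36), an enzyme of NAD synthesis. The 10 lowest were POFUT3 (-4.58), ZNF404 (-3.56), ASAP2 (-2.86), CDIP1 (-2.72), FAM167A-AS1 (-2.62), RAB38 (-2.56), LYST (-2.55), CD79B (-2.54), the serotonin receptor HTR2B (-2.51) and the protease urokinase, PLAU (-2.44). Of these 20 genes, CEMIP2 and NAMPT had more than 1 probe.

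MYC targets made up the list that stood furthest from random lists in RC-K8. Its 33 measured members had a median log2 difference of 0.91, above all 10000 matched random lists, with 32 members above 0 and 14 at 2-fold higher. These included ODC1 (1.61), the rate-limiting enzyme of polyamine synthesis, the nucleolar helicase DDX21 (1.59), lactate dehydrogenase LDHA (1.34), NOP56 (1.32), CAD (1.25), which starts pyrimidine synthesis, and nucleolin, NCL (1.09). STAT-induced feedback and early target genes had a median of 0.31 (percentile 99.98), with 5 of 22 members at 2-fold higher. Those were SOCS3, MYC, IRF1 (1.90), BATF (1.68) and BCL6 (1.59), a transcriptional repressor needed for the germinal centre program. Stress and unfolded protein response genes had a median of 0.33 (percentile 99.7; 0.195 with the probe of highest mean ratio), with ATF3 (1.06) and SESN2 (1.01) 2-fold higher and HERPUD1 (-1.14) 2-fold lower.

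B cell markers and NF-kappaB targets were lower in treated RC-K8. NF-kappaB targets had a median of -0.55, below all 10000 random lists, with 15 of 20 members below 0 and NFKBIE (-1.34) and TNF (-1.06) 2-fold lower; the median was -0.30 after the loess correction. B cell markers also had a median of -0.55 (percentile 0.525), with CD79B and the kinase BTK (-1.51) lower and the coactivator POU2AF1 (1.28) higher among 9 measured. Plasma cell differentiation genes had a median of -0.41 (percentile 0.58, and -0.21 with the probe of highest mean ratio). The measured members were split, with 5 above 0 and 6 below, and no member was at 2-fold. PRDM1, also on this list, had a value on the treated RC-K8 array alone and is not in the median. Outside these lists' calls, the germinal centre genes ELL3 (-1.32) and GCSAM (-1.18), HLA-DMB (-1.35) of class II antigen loading and the T cell gene CD28 (-1.26) were lower, and GBP2 (1.51) and ELF3 (1.16) were higher.

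The remaining lists lay within the middle 95% of random lists in RC-K8. Their median log2 differences were 0.02 for IL-21 receptor and JAK-STAT components, -0.08 for interferon-stimulated genes, -0.00 for anti-apoptotic genes, -0.11 for pro-apoptotic BCL2 family genes and -0.05 for death receptor and caspase genes. They were -0.03 for cell cycle genes, -0.09 for CDK inhibitors, 0.03 for p53 targets, -0.02 for germinal centre B cell genes, -0.04 for antigen presentation genes and 0.14 for ribosomal protein genes. Marker medians were -0.33 for T and NK cells, -0.14 for myeloid cells, -0.12 for epithelial cells, -0.25 for fibroblasts and -0.19 for hepatocytes. Several of these small medians took the other sign under another setting, so no direction is read from them.

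Among the study genes in RC-K8, STAT3 was 2.10-fold higher on 3 probes (log2 1.07) and SOCS1 was 0.84 higher on 2. BCL2 (-0.00) and the pro-apoptotic BCL2L11 (0.03) differed little, as did IL21R (0.08), JAK1 (-0.23), JAK3 (-0.20) and IL2RG (-0.39). PRDM1, the regulator of plasma cell differentiation, had a value on the treated RC-K8 array alone, a centred log2 ratio of 1.47, so no difference could be formed.

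**Figure D1:**
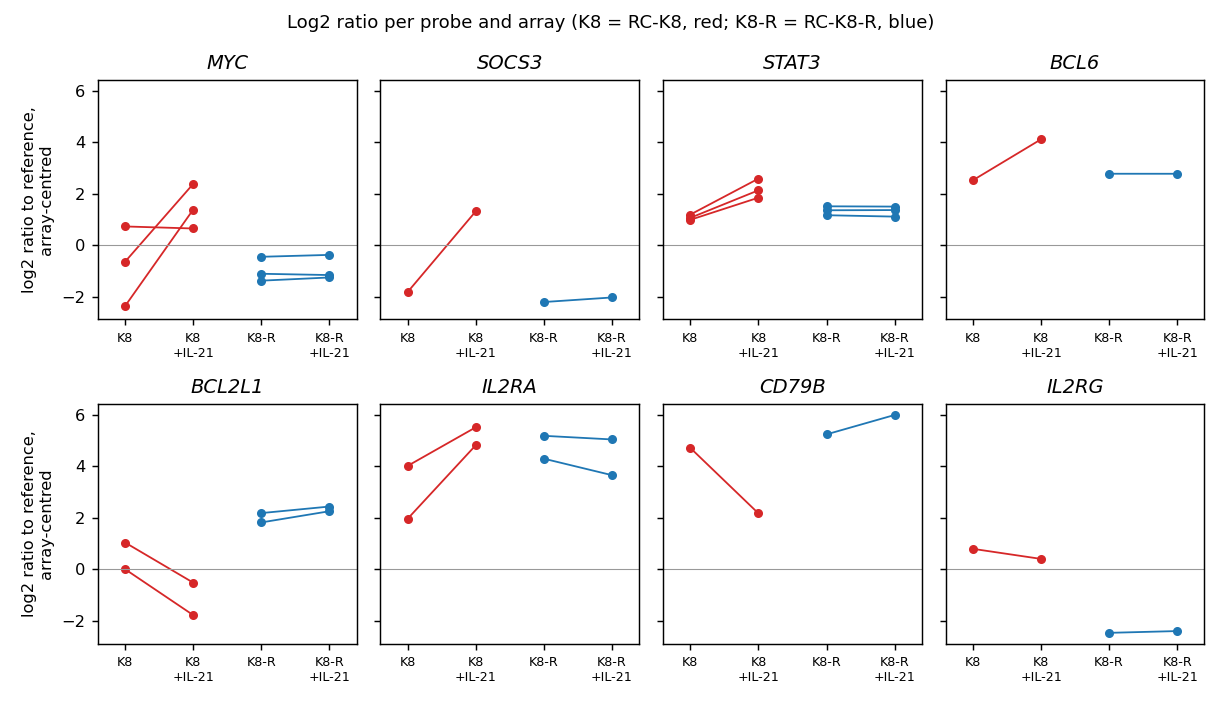
Centred log2 ratio to the reference RNA for each probe with a value on all 4 arrays, by array, for 8 genes; each line joins the untreated and IL-21 arrays of 1 cell line (red RC-K8, blue RC-K8-R). MYC was 3.02 and 3.74 higher with IL-21 in RC-K8 on 2 of its 3 probes, and IL2RG was near -2.4 on both RC-K8-R arrays.

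The next comparison asked how RC-K8-R responded to the same treatment. Study genes that were higher with IL-21 in RC-K8 differed little there: log2 differences were 0.07 for MYC, 0.18 for SOCS3, -0.01 for STAT3, -0.00 for BCL6 and 0.18 for SOCS1. A further STAT3 probe, left out because it was blank on untreated RC-K8, went against this. It was 0.715 higher with IL-21 in RC-K8-R, at 1.82 untreated and 2.53 treated. BCL2L1 was 0.34 higher on 2 probes, against -1.67 in RC-K8. Of the 10 highest genes of RC-K8, HIC1 (1.51) and ZIC1 (1.2), each with 1 probe and a mean log2 ratio below -2, were 2-fold higher in RC-K8-R as well. There were 46 genes at 2-fold higher and 81 at 2-fold lower. Of these genes, 77.2% had a mean log2 ratio below -2 over the 4 arrays, against 8.63% of all genes. A single probe stood behind 112 of the 127, and 13 of the other 15 had 2 or more probes in the same direction.

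The highest named genes in RC-K8-R with IL-21 were EHD3 (2.88), GXYLT2 (2.87), CSGALNACT1 (2.52), PRUNE2 and TSC22D1 (both 2.42), PNMT (2.10), XAGE3 (2.02), SPAG16 (1.93) and the proteoglycan SDC2 (1.85). The lowest were GPD2 (-3.31), VAT1L (-2.94), KCNS3 (-2.78), SH3RF3 (-2.70), the epidermal growth factor receptor EGFR (-2.51), B4GALNT3 (-2.40), RNF130 (-2.37), MICU3 (-2.34), and PDGFRA and SASH1 (both -2.21). EHD3, GXYLT2, CSGALNACT1 and XAGE3 were also among the genes lowest on the untreated RC-K8-R array against RC-K8, which shares that array. List members at 2-fold were the interferon-stimulated genes HERC6 (1.79) and MX2 (1.32) and the collagen gene COL3A1 (-1.5). Probes of a gene disagreed for MX2 (-0.11 and 2.75), COL3A1 (-2.86 and -0.15) and SASH1 (-3.78 and -0.65).

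MYC targets had a median of 0.00 in RC-K8-R with no member at 2-fold, and STAT-induced genes 0.06 with none. NF-kappaB targets had 0.04 and stress genes -0.08, both within the middle 95% of random lists. B cell markers had a median of 0.22 (percentile 99.6), with 7 of 9 members above 0 and none at 2-fold; this was 0.05 at the lowest over the alternative settings. The JAK-STAT components were at 0.06, with IL21R at 0.12, IL2RG at 0.07, JAK1 at 0.09 and JAK3 at -0.18. BCL2 was at -0.04 and BCL2L11 at 0.11.

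**Figure D2:**
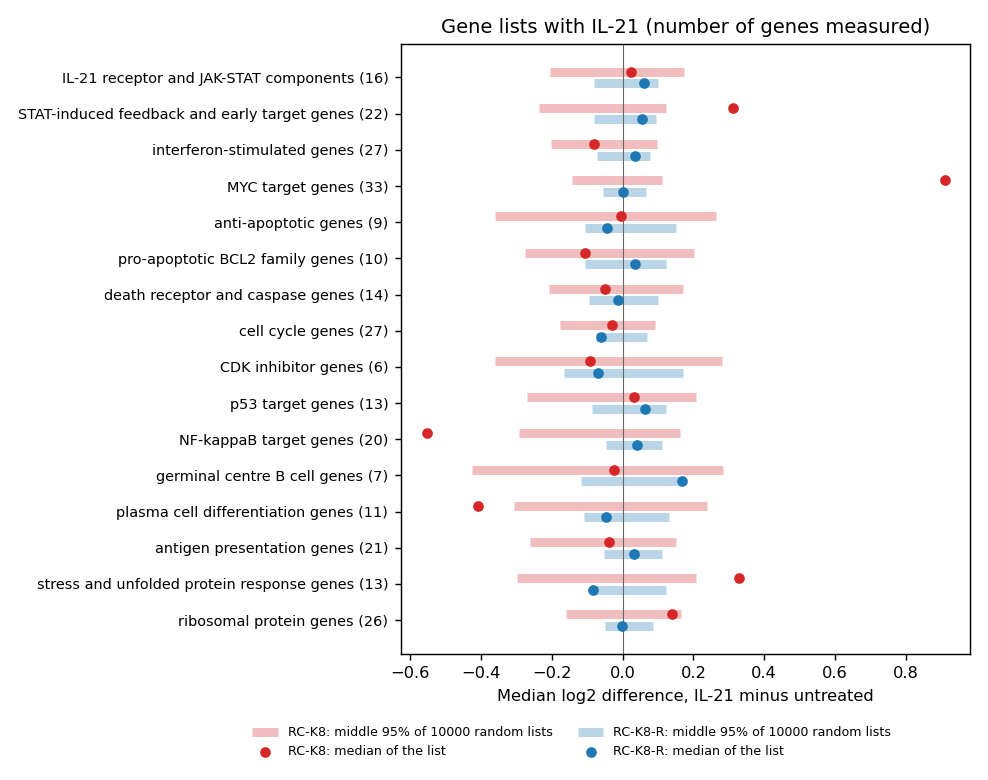
Median log2 difference, IL-21 minus untreated, of each gene list in RC-K8 (red) and RC-K8-R (blue); bars span the middle 95% of 10000 matched random lists, and the number of genes measured stands beside each name. MYC targets lie at 0.91 in RC-K8 and 0.00 in RC-K8-R, and NF-kappaB targets at -0.55 and 0.04.

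Set side by side, the responses of the lines had little in common. Genes 2-fold higher in RC-K8 had a median of 1.27 there and 0.03 in RC-K8-R, and genes 2-fold lower had -1.26 and 0.01. There were 4 genes at 2-fold higher in both lines (0.66 expected for independent lists) and 2 at 2-fold lower in both (1.34 expected), while 3 were higher in RC-K8 and lower in RC-K8-R and 4 the reverse. No expected number was computed for the opposite directions. The expected numbers ignore level. Below a mean log2 ratio of -2 lay 19.7% of the 2-fold genes in RC-K8, 77.2% of those in RC-K8-R and 8.63% of all genes. Across genes, which are not independent replicates, Pearson's r between the responses was 0.026 and Spearman's rho 0.031; the responses share no array.

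The difference of responses, RC-K8-R minus RC-K8, was 2-fold or more for 332 genes in the positive and 309 in the negative direction. It was -3.07 for MYC (0.15 on the probe with the highest mean ratio), -2.96 for SOCS3, -1.06 for STAT3, -1.59 for BCL6, -0.66 for SOCS1 and 2.01 for BCL2L1. POFUT3 (4.69), GXYLT2 (3.79), ZNF404 (3.61), CDIP1 (3.35) and EHD3 (3.31) had the largest positive differences. VAT1L (-3.35), GPD2 (-3.32), SGK1 (-3.26), SPOCK1 (-3.25) and RNF182 (-3.20) had the largest negative ones. MYC targets had a median of -0.90 with 13 of 33 members at 2-fold, below all random lists, among them ODC1 (-1.64), DDX21 (-1.62) and HSPE1 (-1.11). NF-kappaB targets had 0.58 (percentile 99.93), with NFKBIE (1.53), TNF (1.25) and CD40 (1.05) at 2-fold, and B cell markers 0.73 (percentile 99.7), with CD79B (3.29) and BTK (1.79) and, in the other direction, POU2AF1 (-1.23). After the loess correction these medians were 0.23 and 0.33. STAT-induced genes had -0.31 (percentile 0.15; -0.199 with the probe of highest mean ratio). Plasma cell genes had 0.49 (percentile 99.7), with 6 members above 0 and 5 below. That median turned to -0.01 when each gene was read from its probe with the highest mean ratio.

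**Figure D3:**
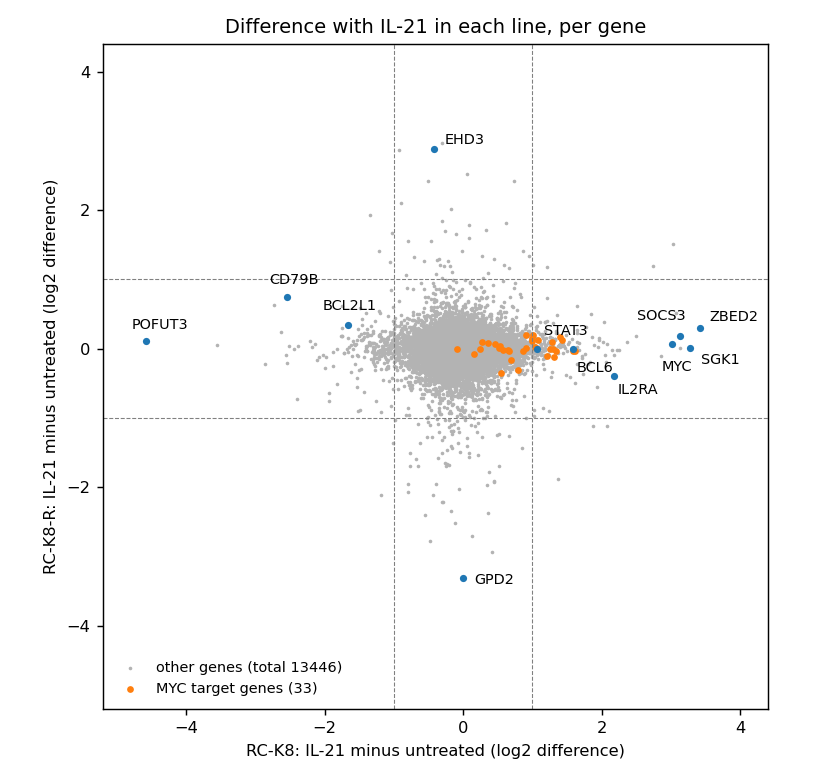
Log2 difference with IL-21 for each of 13446 genes in RC-K8 (horizontal) and RC-K8-R (vertical); dashed lines mark 2-fold, orange points are the 33 MYC targets, and blue points are labelled genes. Few genes were at 2-fold in both lines, 4 higher and 2 lower in both, 3 higher in RC-K8 and lower in RC-K8-R, and 4 the reverse; Pearson's r was 0.026.

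The comparison of untreated lines asked what distinguished RC-K8-R before treatment. RC-K8-R had lower IL2RG, the common gamma chain shared by the receptors for IL-2, IL-21 and related cytokines, and higher BCL2L1, antigen presentation genes and the long noncoding RNA MALAT1. IL2RG was 9.59-fold lower on 1 probe (log2 -3.26), with centred log2 ratios of 0.80 in RC-K8 and -2.46 in RC-K8-R. BCL2L1 was 2.79-fold higher on 2 probes (log2 1.48, SD between probes 0.48), and MALAT1 4.33-fold higher as the median of 5 probes. In all, 450 genes were 2-fold higher and 1368 were 2-fold lower in RC-K8-R.

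The highest genes in untreated RC-K8-R were ATF7-AS1 (3.28), the spliceosomal RNA RNU12 (2.71), the cilia motor gene DYNC2H1 (2.63), DNAI7 (2.60), ATP8A1 (2.28), SECISBP2L (2.24), ZIC1 (2.20), MALAT1 (2.12), RBM33 (2.08) and TIFA (2.05). The lowest were EHD3 (-4.48), XAGE3 (-3.99), the actin-binding CALD1 (-3.87), GXYLT2 (-3.63), RAB38 (-3.60), CSGALNACT1 (-3.48), the dopamine receptor DRD5 (-3.41), IL2RG (-3.26), CXADRP2 (-3.19) and PPP1R14C (-3.16). Not all of the lowest values recurred with IL-21. The difference of responses was 3.79 for GXYLT2 and 3.31 for EHD3, which offsets all or most of their line difference. Their values here thus rest largely on the untreated arrays, whereas IL2RG was also lower with IL-21 (-2.80). The 3 MYC probes disagreed, at -0.47, -1.18 and 0.985, so no direction is read for MYC. Other study genes differed less: SOCS3 -0.39, STAT3 0.29, SOCS1 0.25, BCL6 0.25, IL21R 0.07, JAK1 0.78, JAK3 0.07, BCL2 0.05 and BCL2L11 -0.37. Probes differed in sign for BCL2 (-0.35 and 0.45), SOCS1 (-0.09 and 0.59) and JAK3 (-0.19 to 0.16), so no direction is read for these. The JAK1 probes were at 0.30 and 1.27.

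Antigen presentation genes had a median of 0.64 in untreated RC-K8-R (percentile 99.6), with 19 of 21 members above 0. HLA-DRB1 (1.59), the invariant chain CD74 (1.5), HLA-DMB (1.48) and HLA-DQA1 (1.22, from probes at 0.22 and 2.21) were 2-fold higher; after the loess correction the median was 0.31. Plasma cell genes had 0.57 (percentile 98.5; 0.37 after loess), with JCHAIN (1.26) and MZB1 (1.17) 2-fold higher. Interferon-stimulated genes went both ways: 8 of 27 were 2-fold higher, including SP110 (1.82), ISG15 (1.66) and EPSTI1 (1.65), and 9 were 2-fold lower, including MX2 (-2.78, from probes at -1.09 and -4.48), HERC6 (-2.44), USP18 (-1.99, from probes at -1.29 and -2.69) and GBP4 (-1.45). NF-kappaB targets had a median of 0.14 (percentile 1.00), which turned to -0.41 after the loess correction; NFKBIE was higher (1.73) and the chemokine CCL4 lower (-2.01).

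Markers of other cell types had medians below 0 in RC-K8-R, on arrays with the wider range of ratios, but myeloid markers alone lay outside the range of random lists at their level. Medians were -0.87 for T and NK cells (percentile 16.5), with CD3D (-2.17), CD3G (-2.03) and CD3E (-1.22) 2-fold lower, and -0.99 for myeloid cells (percentile 0.845), with CTSG (-1.48). They were -1.17 for epithelial cells (percentile 5.57), with KRT19 (-2.91) and EPCAM (-1.76), -0.77 for fibroblasts (percentile 33.1) and -0.998 for hepatocytes (percentile 14). After the loess correction T and NK cell markers were at -0.73, myeloid markers at -0.997, epithelial markers at -0.44, fibroblast markers at 0.08 and hepatocyte markers at -0.09. B cell markers had a median of 0.65 (percentile 95.5; 0.27 after loess), with MS4A1, the CD20 gene (1.48), PAX5 (1.27) and BLK (1.05) 2-fold higher. Other list members at 2-fold included JUNB (1.31), MDM2 (1.02), GCSAM (1.91), DNAJB1 (1.07), RPS14 (1.06), FOS (-1.43), the pro-apoptotic BOK (-1.77), CDKN2B (-1.14) and S1PR2 (-1.38). Of the 76 genes named by the rule at 2-fold in this comparison, 23 were smaller by over 1.5 times after loess and none reversed.

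**Figure D4:**
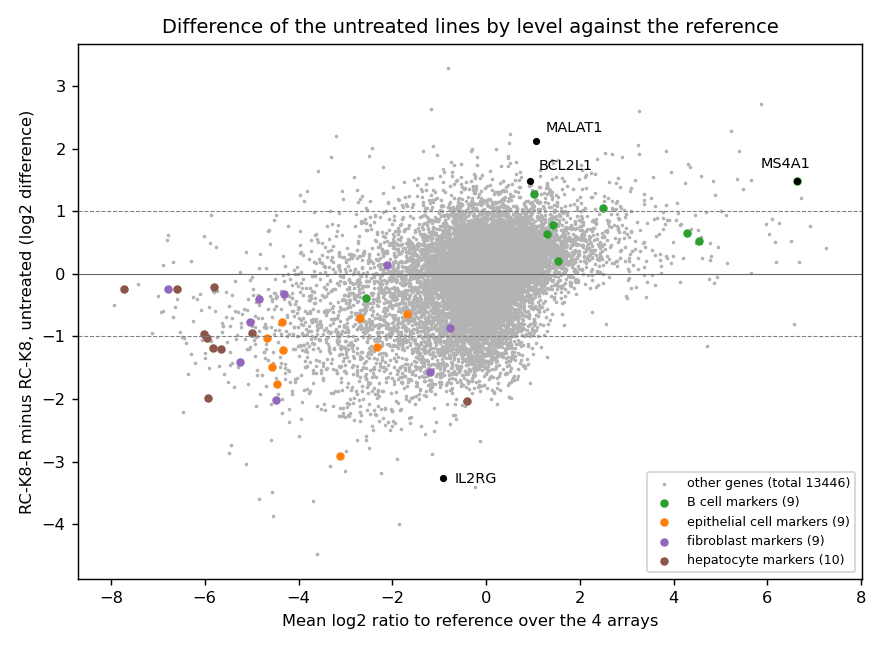
Log2 difference of untreated RC-K8-R minus RC-K8 for each of 13446 genes against its mean log2 ratio to the reference over the 4 arrays; dashed lines mark 2-fold, and coloured points are cell type markers. Genes far below the reference tend to lie below 0, and IL2RG lies at -3.26.

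The last comparison set the lines against each other after IL-21. Treated RC-K8-R had lower MYC, MYC targets and SOCS3 than treated RC-K8, and higher BCL2L1 and B cell markers. The log2 differences were -2.64 for MYC (-1.03 on the probe with the highest mean ratio), -3.35 for SOCS3, -1.34 for BCL6, -0.77 for STAT3 and 3.49 for BCL2L1, an 11.3-fold difference. Further probes, left out because they were blank on an untreated array, gave -1.21 for SOCS3 and, in the other direction, 0.595 for STAT3. IL2RG was again lower (-2.80), and JAK1 was higher (1.11, from probes at 0.36 and 1.86). There were 1004 genes at 2-fold higher and 1389 at 2-fold lower.

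POFUT3 (5.61), ZNF404 (4.43), the kinase TEC (4.02), DYNC2H1 (3.86) and CD79B (3.82) were the highest genes in treated RC-K8-R, and ZBED2 (-4.64), VAT1L (-4.22), LY96 (-4.09), TCEAL3 (-3.91) and RNF130 (-3.72) the lowest. MYC targets had a median of -0.76, below all random lists, with 33 of 33 members below 0 and 12 at 2-fold. B cell markers had 1.41 (percentile 99.9), with 7 of 9 at 2-fold, including MS4A1 (2.21) and PAX5 (2.26); after the loess correction the median was 0.68, MS4A1 was at 0.68 and CD37 reversed. STAT-induced genes had -0.60 (percentile 0.03; -0.38 with equal deviation per array), with 6 of 22 at 2-fold lower and IRF4 (1.37), JUNB (1.35) and CD274 (1.12) at 2-fold higher. Antigen presentation genes had 0.77 (percentile 98.6) with 7 of 21 at 2-fold higher, but 0.15 after the loess correction, where HLA-DRA (1.30) and HLA-DQB1 (1.11) turned to -0.32 and -0.35. Stress genes had -0.32 (percentile 1.25), with ASNS (-1.25) and SESN2 (-1.13) lower and HERPUD1 (1.62), DNAJB1 (1.32) and HSPA5 (1.10) higher. Of the 99 genes named by the rule at 2-fold here, 27 were smaller by over 1.5 times after loess, 4 of them reversed.

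Much of the line difference recurred on separate arrays. Of the genes 2-fold different between untreated lines, 316 higher (33.6 expected for independent lists) and 872 lower (141 expected) were so with IL-21 as well, or 70.2% and 63.7%. Across genes, Pearson's r between the untreated and treated line differences, which share no array, was 0.783 and Spearman's rho 0.794. Both differences rose with the mean log2 ratio, at slopes of 0.202 and 0.192, and this shared trend can raise the overlaps and the correlation. After the loess correction r was 0.751. Any difference between arrays that goes with the line would recur as well. The mean line difference and the mean IL-21 response had an r of 0.083 and a rho of 0.120 across genes.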

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

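In this part, the tests of noise, scaling, mislabelling, level and ratio range were chosen after the results had been seen, and the test of a reduced RC-K8 response in RC-K8-R before. Differences of opposite sign in the lines were not tested, since each line has 1 array per condition.

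With IL-21, 9 of the named genes differed by 1.5-fold or more in both lines, in opposite directions. CD79B was -2.54 in RC-K8 and 0.75 in RC-K8-R, a difference of 3.29, at a mean log2 ratio of 4.53. The other genes lower in RC-K8 and higher in RC-K8-R were CDIP1 (difference 3.35), GXYLT2 (3.79), MX2 (2.03), PNMT (2.99) and SPAG16 (3.28). Those higher in RC-K8 and lower in RC-K8-R were ELF3 (-2.02), RNF182 (-3.20) and SPOCK1 (-3.25). Each had 1 probe except MX2, whose 2 probes disagreed in RC-K8-R. Apart from CD79B and SPAG16 (-1.68), their mean log2 ratios lay below -2, from -2.49 for MX2 to -4.91 for CDIP1. At such levels noise is a candidate explanation, as for other genes far below the reference. CDIP1, GXYLT2, RNF182 and SPOCK1 were also named for a large difference of responses, a choice that favours opposite signs. Among all genes, 39 differed by 1.5-fold or more in opposite directions and 48 in the same direction.

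The first pattern weighed is the many 2-fold differences with IL-21 in RC-K8 and the few in RC-K8-R. Random array noise would leave the probes of a gene unrelated, but the responses of 2 probes of the same gene correlated at 0.529 in RC-K8 across 4379 genes (at most 0.052 in 1000 shuffles), against 0.110 in RC-K8-R (at most 0.058). That argues only against noise of single probes. Another difference between the untreated and treated RC-K8 cultures would give the same agreement and cannot be told apart from IL-21 here. The scaling of the arrays does not account for the pattern, since the counts kept it under each of 3 scalings. Genes 2-fold higher and lower were 275 and 254 in RC-K8 against 45 and 61 in RC-K8-R with quantile normalization. They were 235 and 260 against 46 and 61 with equal deviation, and 221 and 194 against 46 and 80 with loess. The median of MYC targets in RC-K8, a list picked for its distance from random lists, was 0.955 or more under each. A treated RC-K8-R array that held untreated cells stays open: 4 genes were 2-fold higher in both lines, and cells that do not respond would give as few. Loss of the IL-21 response in RC-K8-R, the difference named by the design, may account for the pattern but cannot be told apart from that with 1 array.

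The second pattern is the 127 genes at 2-fold with IL-21 in RC-K8-R. Noise of probes far below the reference is a candidate explanation, since 77.2% of these genes had a mean log2 ratio below -2, against 8.63% of all genes. It was not shown for all of them. Across all genes with 2 or more probes, 2 probes of a gene correlated at 0.110, above the 0.058 of shuffles. That value is not for the 127 genes alone. Of the 15 such genes at 2-fold, 13 had probes in the same direction. This cannot decide the question, since choosing genes by the median of their probes favours probes of the same direction. A response like that of RC-K8 at reduced size was not decided, as 55.1% of the genes had the same sign in RC-K8 (95% exact binomial interval 46.0 to 64.0%, treating genes as independent). The share differed by direction, with 18 of the 46 higher and 52 of the 81 lower genes, and the median RC-K8 response was below 0 in both sets (-0.20 and -0.16).

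The third pattern is the 1818 genes 2-fold different between untreated lines, with marker medians of epithelial cells, fibroblasts and hepatocytes below 0 in RC-K8-R. Whether the wider ratio range of the RC-K8-R arrays makes these marker medians stays open: the median of 28 markers went from -0.99 to -0.26 (SD over markers 0.81) after the loess correction, but that correction removes the average difference at their level, here -0.81, so it fixes most of the outcome. The range does not account for all of the line difference. After the correction 1529 genes were 2-fold different, among them 295 of the 450 higher and 1001 of the 1368 lower genes. Whether the range came from the cells or the arrays stays open, since it goes with the line.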

How the results depend on the processing

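The setting for mean log2 ratio was chosen after the data had been seen, and the other settings before. Leaving out a replicate was not possible with 1 array per group. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. An additive fit of line and treatment over the 4 arrays, whose only residual is the difference of responses, was not run. The signal over background behind each value is not known here.

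Counts of 2-fold genes stayed within 1.5 times under centring, quantile, equal deviation, loess, mean of probes, highest probe and genes on the arrays compared. Counts that moved further are given as higher and lower, in the order IL-21 in RC-K8, IL-21 in RC-K8-R, difference of responses, untreated lines and treated lines. At 1.5-fold they were 782 and 798, 162 and 280, 1089 and 1093, 1822 and 2768, and 2424 and 3037. At 3-fold they were 49 and 43, 17 and 29, 85 and 75, 57 and 344, and 254 and 391. With every probe as its own feature they were 424 and 404, 80 and 149, 618 and 612, 1242 and 2196, and 2144 and 2242. With 2 or more probes in the same direction they were 58 and 55, 2 and 11, 71 and 69, 137 and 206, and 339 and 234. Read as natural logs they were 548 and 530, 105 and 180, 750 and 792, 1242 and 2382, and 1932 and 2522. The thresholds, the number of features and the log base change these counts by construction. For genes with a mean log2 ratio of -2 or more, the RC-K8-R response had 9 higher and 20 lower genes.

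After the loess correction, 4 genes of the treated line comparison reversed: CCR7 to -0.13, CD37 to -0.074, HLA-DQB1 to -0.35 and HLA-DRA to -0.32. With the probe of highest mean ratio, MYC reversed to -0.079 in RC-K8 and 0.15 in the difference of responses, MX2 to -0.11 in RC-K8-R, HLA-DQA1 to 0.093 and the plasma cell median to -0.012 in the difference of responses. The NF-kappaB median of untreated lines (0.14) reversed to -0.37 with quantile, -0.25 with equal deviation and -0.41 with loess. For the probe choice the cause is the disagreement of probes; for the scalings the cause was not tested. Tolerance for other values, single-probe genes and list medians included, was the comparison's median SD between probes over the 4379 genes with 2 or more probes: 0.161, 0.119, 0.199, 0.306 and 0.308 in the order above. Counted once per setting over 7 settings, the 300 gene values called at 2-fold moved by no more than it 1382 times and further without changing sign 710 times, 300 of these under the natural log. The 21 called list medians did so 119 and 24 times, 12 of the latter under the natural log. Of the list percentiles, 19 of 110 crossed into or out of the middle 95% when random lists were not matched. The correlation of responses ranged from 0.022 to 0.033 and that of line differences from 0.729 to 0.785. Under loess, 192 of the 193 higher and 188 of the 223 lower genes in RC-K8 were the same, and 295 of 450 and 1001 of 1368 between untreated lines.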

Other observations

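The gene lists in this part and the test of IL2RG on separate arrays were chosen after values had been seen; both tests of a kept IL-21 state were written before. In treated RC-K8, lists of genes for amino acid uptake and use had medians above 0. Amino acid transporters had a median log2 difference of 1.07 over 11 genes, 6 of them at 2-fold, including SLC3A2 (1.40) and SLC7A5 (1.16), which form the leucine transporter LAT1, and the cystine transporter SLC7A11 (1.18). Aminoacyl-tRNA synthetases had a median of 0.44 with 18 of 19 above 0, 2 at 2-fold and WARS1 (1.30) the highest. Serine and one-carbon genes had 0.34, with 7 of 10 above 0 and 3 at 2-fold, including PSAT1 (1.27) and MTHFD2 (1.16). Glycolysis genes had 0.24, with 15 of 19 above 0 and 3 at 2-fold, including HK2 (1.80) and ENO1 (1.34). In RC-K8-R these medians were 0.02, 0.02, -0.03 and 0.00.

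A list for protein folding and export, chosen after SYVN1, HERPUD1 and PDIA4 had been seen, had the other sign, while the stress and unfolded protein response list fixed beforehand was at 0.33. The endoplasmic reticulum quality control and secretion list had a median of -0.51 in treated RC-K8, with 17 of 20 below 0 and 6 at 2-fold lower, among them the ubiquitin ligase SYVN1 (-1.35), CKAP4 (-1.22) and PDIA4 (-1.04). It was -0.01 with IL-21 in RC-K8-R, 0.70 higher in untreated RC-K8-R than in RC-K8, and 1.16 higher with IL-21, where 13 of 20 were at 2-fold. B cell receptor signalling genes had -0.44 in RC-K8 (-0.285 at the smallest over the settings), with CD79B, IGLL1 (-2.13), TEC (-1.74), BTK and IGLL5 (-1.08) 2-fold lower and the kinase LYN (1.86) higher, and 0.17 in RC-K8-R. Cytokine receptor genes had a median of -0.02 in RC-K8, but IL2RA, the alpha chain of the IL-2 receptor, was 2.18 higher and IL10RA was -1.01. IL2RA was also 1.75 higher in untreated RC-K8-R than in untreated RC-K8.

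If RC-K8-R did not respond, which 1 treated array cannot show, lower IL2RG is a candidate explanation, since IL-21 signals through this chain. It was not the artefact of a single array: the difference was -3.26 on the untreated arrays and -2.80 on the separate IL-21 arrays, though from the same probe. IL21R was at 0.07 and 0.12 in these comparisons. Whether less IL2RG mRNA lowers the receptor at the cell surface was not measured here.

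A different hypothesis was that RC-K8-R, selected under IL-21, may have kept the IL-21 state of RC-K8. Untreated RC-K8-R was set against the midpoint of untreated and treated RC-K8, which shares no array with it. Over the 193 genes 2-fold higher with IL-21 in RC-K8 its median lay at -0.36, below all 10000 matched random lists and on the side of untreated RC-K8, where -0.63 would equal untreated cells. Over the 223 lower genes it lay at 0.85, above all random lists, also on the side of untreated RC-K8. The tests argue against a fully kept state of these genes as sets, with 49 of the 193 and 46 of the 223 nearer to treated cells. A partial shift of the higher genes stays open: 147 of the 193 lay above untreated RC-K8, at a median position of 0.24 between untreated (0) and treated (1), against -0.10 for the lower genes, but the genes were chosen on that same untreated array. IL2RA in RC-K8-R was at 4.30 and 5.19 on its 2 probes, against 1.97 and 4.02 in untreated and 4.83 and 5.52 in treated RC-K8.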
